A study of Mus musculus with 3 samples.

How the data were processed

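RNA of 3 stable 4T1 lines was measured on 3 two-colour arrays, 1 per line. Per the labels' protocols, total RNA was extracted with column kits, sample RNA was labelled with Cy5 and a commercial universal mouse reference RNA, a mix of cell lines, with Cy3, and the same orientation was used on every array, so a ratio is sample over reference and dye effects of a probe cancel in differences between arrays. The 3 arrays were on the same slide and in the same scan per the file headers, so slide and scan do not separate the groups. Each array held 62976 spots, of which 59305 were not controls.

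The deposited scanner files were made with Agilent Feature Extraction, version 11.0.1.1 per the file headers and 9.5.3.1 per the submitters' processing notes. They hold, per spot, median signal intensity and median local background intensity for both channels on a linear scale, neither background-subtracted nor dye-normalized per the file headers. The plan named mean signals, but the files used here gave medians, which were used. They also hold 0/1 flags set by Feature Extraction and a log10 ratio of red over green that the authors' software made after background subtraction, removal of a spatial trend and dye normalization. The authors' deposited value table gives 1 log2 ratio per probe. Its columns equalled the scanner log10 ratio on the log2 scale, within 0.002, at 54165, 53388 and 52507 single-spot probes of the vector, SNAIL-labelled and SNAIL+FBXO11-labelled arrays. The remaining 1062, 1848 and 2733 all had a scanner ratio of 0. Scale and direction are thereby settled, and the column medians were 0.155, 0.156 and 0.181, with no further centring stated. Columns of samples outside the series numbered 0.

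From the intensities, background was corrected with normexp (offset 50, fitted on all spots) in limma 3.58.1 under R 4.3.3, and log2 ratios were normalized within each array by loess with control spots at weight 0. Control spots and spots flagged as outliers were then left out. Spots of a probe were averaged, and so were the probes of a gene. A probe entered a comparison if the sample channel was well above background, per the flags, on both arrays. Signals per channel were also quantile-normalized across the arrays, to give the sample channel alone and the reference channel alone. Probes carry accessions, not gene names. These were matched without versions to the RefSeq gene table of GRCm38.p6, which named 27509 of 55681 probes (49.4%) and 20887 genes. The array annotation uses the build mm9, so no coordinates are given. Of 4439 genes with 2 or more measured probes in the SNAIL against vector comparison, 91 were past 2-fold, and in 3 of these the probes had both signs.

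With 1 array per group there is no p-value. Values are differences of log2 ratios between 2 arrays, and a gene was counted as higher or lower at 2-fold. A gene above background on 1 array of a pair only has a bound: its normalized log2 signal on the brighter array minus the higher of its own signal and the lowest signal of any probe well above background on the dimmer array, per channel after loess and Aquantile. Such bounds are open to dye bias. For a fixed gene list, the median difference is given with its percentile among 10000 random lists of the same size matched over 20 bins of mean intensity, which describes these arrays and is not a test. In all, 27 lists were fixed before the data were examined, with 761 entries, and described in 3 comparisons. They cover epithelial junctions, keratins and surface genes, epithelial regulators, transition factors, mesenchymal genes, matrix, proteases, SNAIL-repressed targets, TGF-beta response, cell cycle, p53 targets, reported FBXO11 substrates, SCF ubiquitin genes, interferon response, antigen presentation, cytokines, hypoxia and glycolysis, endoplasmic reticulum stress, sterol synthesis, luminal and basal mammary genes, stemness, leukocyte, endothelial and fibroblast markers, housekeeping genes and cytosolic ribosomal proteins.

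Genes were named by a rule fixed at the same time. It took Snai1, Fbxo11, Cdh1, Epcam, Vim, Fn1, Cdh2, Zeb1 and Zeb2 whatever their values. It took the 10 largest rises and falls past 2-fold among annotated genes with unsaturated signal and probes of like sign (5 for SNAIL+FBXO11 against vector) and up to 5 bounds each way. From each list it took up to 4 members past 2-fold, or the member with the largest difference. Some genes that the rule takes are not reported here.

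Technical spread was taken from the 399 probes printed at 10 spots each. The procedure was tested on simulated data for the SNAIL against vector comparison, with 18138 genes run. All 50 genes planted at each of 2.5-fold, 4-fold and 8-fold were called in the right direction, 0 of 50 planted at 1.5-fold were called, and 0 of 17938 unchanged genes were called. That last count is not a rate of false calls for the measured arrays. In their reference channel, with the same RNA, 20 genes differed at least 2-fold between the SNAIL-labelled and vector arrays. Of 20 random lists 19 fell between percentiles 5 and 95, and all 5 lists shifted by 0.5 were above percentile 99. Simulations and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The number of arrays limits the precision of every value.

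Alternatives fixed before the data were examined were normexp with offset 0, the Feature Extraction log ratio, the authors' value table, median centring in place of loess, Aquantile scaling, the sample channel alone, no filter on dim probes, both channels above background on all arrays, the brightest probe of a gene, and rules of 1.5-fold and 3-fold. Chosen after seeing the data were a normexp fit without spots of non-uniform background, a limit of 2-fold on the difference of the reference channel, and the exclusion of spots with an outlying background.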

Results

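The data were 3 two-colour Agilent oligonucleotide arrays of 4T1 cells, a mouse mammary carcinoma line. Stable lines had been made with pLEX lentiviruses and puromycin selection and were harvested near confluence without the drug. The first line carried empty vector, the second SNAIL (the product of Snai1, a zinc-finger repressor of epithelial genes), and the third SNAIL together with FBXO11, the substrate-binding F-box subunit of an SCF ubiquitin ligase. Per the labels, the vector line and the SNAIL+FBXO11 line had an epithelial phenotype and low invasion, and the SNAIL line a mesenchymal phenotype and high invasion. Each line was measured on 1 array in the Cy5 channel, with universal mouse reference RNA in the Cy3 channel. There were no replicates, so no comparison below has a test, and "rose" and "fell" mean a difference of at least 2-fold between 2 arrays, which is a rule of size. The sample channel was well above background at 86.9% of the spots on the vector array, 81.6% on the SNAIL-labelled array and 78.1% on the SNAIL+FBXO11-labelled array, and 18136, 17509 and 17650 genes could be compared for SNAIL against vector, SNAIL+FBXO11 against SNAIL, and SNAIL+FBXO11 against vector.

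The genes carried by the viruses were looked at first. The Snai1 probe differed by -0.37 on the log2 scale between the SNAIL-labelled and vector arrays and by 0.21 between the SNAIL+FBXO11-labelled and vector arrays. The Fbxo11 probe differed by 0.40 and -0.09 in the same comparisons. Between the SNAIL+FBXO11-labelled and SNAIL-labelled arrays the Snai1 probe differed by 0.59 and the Fbxo11 probe by -0.49 (-0.38 in the sample channel alone). Neither probe rose on an array labelled for its gene. Where these probes lie relative to the viral inserts, and from which species the inserts came, is not given in the sources used here, so the probes do not check the labels, and each array is called by its label throughout. Directions below rest on those labels.

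The technical spread over spots was small beside a 2-fold difference. Among 399 probes printed at 10 spots each, the median SD over spots of the SNAIL minus vector log2 difference was 0.14 for probes of mean log2 intensity under 8 and 0.04 for those over 12. Simulated arrays that differed by this spot noise alone gave 0 genes past 2-fold in each of 100 draws. Spots of a probe share an array, so this noise leaves out differences between arrays. In the reference channel, which held the same RNA on every array, 20 genes differed at least 2-fold between the SNAIL-labelled and vector arrays, against 609 in the sample channel. The SD over genes was 0.15 in the reference channel and 0.42 in the sample channel, so small differences of single genes may be technical. Spread between cultures was not measured.

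The first comparison, SNAIL against vector, asks what changed in the line labelled mesenchymal. Many epithelial junction genes were lower on the SNAIL-labelled array. Of 37 measured genes of tight junctions, adherens junctions and desmosomes, 18 fell and 0 rose. Among them were the desmosomal plakophilin Pkp2 (8.37-fold lower), the claudin Cldn7 (6.16-fold lower), occludin, Ocln (4.97-fold lower over 2 probes, at -2.32 and -2.30), and the tight junction protein cingulin, Cgn (4.81-fold lower). The list's median difference was -0.75, at percentile 0 among 10000 random lists matched on intensity, and it stayed below 0 in each of the other settings tried. E-cadherin, Cdh1, was lower by ratio, at -1.29 ± 0.20 (SD over 10 spots of 1 probe), and at -2.48 ± 0.05 in the sample channel alone, but at -0.70, under 2-fold, with the Feature Extraction ratio. At the Cdh1 spots the reference channel was lower as well, at -1.03, so the ratio gave the smaller difference. The same held at 22 probes that were over 16-fold brighter in the sample channel than in the reference channel and fell in the sample channel, where the reference channel had a median difference of -0.54.

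Other epithelial genes went the same way. Of 40 measured keratin and epithelial surface genes, 12 fell and 1 rose, and the median difference was -0.66 (percentile 0). The laminin-332 chain Lamb3 was 5.24-fold lower, the apical transport protein Mal2 6.68-fold lower and the small GTPase Rab25 3.91-fold lower, while the keratin Krt23 was 4.83-fold higher. With the Feature Extraction ratio Mal2 was at -1.58 and Krt23 at 4.13, and Rab25 was at -2.86 in the sample channel alone. The adhesion molecule Epcam was 3.25-fold lower. Of 18 measured genes reported as SNAIL-repressed targets, 8 fell and 0 rose, with a median of -0.59 (percentile 0), including the polarity protein Crb3 at -2.01 (probes at -2.86 and -1.17) and the claudin Cldn4 at -1.77. This list shares members with the junction list, among them Cdh1, Cldn7, Ocln, Cldn4, Crb3 and Epcam. Of 21 measured transcription factors and splicing regulators of epithelial identity, 3 fell: Grhl1 (-1.16, and -2.67 with the Feature Extraction ratio), Ovol1 (-1.08) and Foxa1 (-1.06). The list's median was -0.11, which moved to -0.56 with each array centred on its median in place of loess. With that centring the medians of the keratin and surface genes and of the SNAIL-repressed targets were -1.12 and -1.20.

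Mesenchymal genes changed in smaller numbers. Of 35 measured mesenchymal adhesion and cytoskeleton genes, 4 rose and 1 fell. The intermediate filament vimentin, Vim, was 3.63-fold higher, the growth factor receptor Pdgfra 4.78-fold higher and the calcium-binding protein S100a4 2.84-fold higher over 2 probes, while the membrane linker moesin, Msn, was 2.24-fold lower. S100a4 was under 2-fold with median centring (0.91) and in the sample channel alone (0.92), and Msn in the sample channel alone (-0.77). Their median was 0.22 (percentile 99.8), but -0.15 with median centring. Of 43 measured extracellular matrix genes, 4 were past 2-fold higher and 1 lower. Among them the collagen Col5a1 was at 1.99, Sparc, a matrix glycoprotein, at 1.96, and periostin, Postn, at -1.29. A further member, Loxl3, was at 2.43 by ratio, where its sample channel was lower, at -1.84, and its reference channel lower still, at -3.94, so no rise is read from it. The matrix list's median was 0.13 (percentile 94.4), and it was -0.24 with median centring and 0.05 with the normexp fit chosen after seeing the data. Fibronectin, Fn1, was at 0.75, N-cadherin, Cdh2, at 0.25 and Zeb1 at 0.23, all under 2-fold. With median centring Cdh2 was at -0.15 and Zeb1 at -0.14, and Zeb1 was at -0.37 with the Feature Extraction ratio. Of 23 measured transcription factors of the epithelial to mesenchymal transition, Twist1 (1.14) and Zeb2 (1.07, with probes at 0.78 and 1.35) rose and Sox9 fell (-1.05 ± 0.07, SD over 10 spots), and the list's median of 0.23 turned below 0 with median centring and with the authors' ratios. With median centring both Twist1 (0.80) and Zeb2 (0.86) were under 2-fold. Of 27 measured matrix protease and protease inhibitor genes, 4 rose and 0 fell, namely Mmp3 (9.83-fold), Adamts4 (2.65-fold), Mmp10 (2.30-fold) and Mmp13 (2.12-fold), with a median of 0.15 that was -0.08 with median centring. There Mmp10 (0.90) and Mmp13 (0.98) were under 2-fold, and Mmp13 also in the sample channel alone (0.73). Of 28 measured genes of the TGF-beta response, Smad6 (1.28), Tgfbr3 (1.21) and Tgfb2 (1.08) were among 4 that rose, and follistatin, Fst, (-1.86) was among 2 that fell, while the list's median of 0.15 was below 0 with median centring, where Smad6 (0.95), Tgfbr3 (0.86) and Tgfb2 (0.76) were under 2-fold.

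Many antigen presentation genes were higher. Of 19 measured genes, 9 rose, 0 fell and 18 were above 0, with a median of 0.86 (percentile 100; 0.56 with median centring). The immunoproteasome subunits Psmb8 and Psmb9 were 6.80-fold and 2.73-fold higher, the non-classical class I gene H2-M3 2.46-fold and the class I light chain B2m 2.38-fold, the last 2 being under 2-fold with median centring (0.94 and 0.75). The class I transactivator Nlrc5 averaged 1.34 over probes that disagreed, at 0.03 and 2.65. The list's median stayed above 0 in each of the other settings.

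Over all genes, 361 rose and 220 fell on the SNAIL-labelled array. The largest rises after Mgp, the matrix Gla protein (30.9-fold), were in the secreted protease inhibitor Slpi (12-fold), the small GTPase Rab7b (10.4-fold), Mmp3, the water channel Aqp1 (9.41-fold), the extracellular superoxide dismutase Sod3 (7.08-fold), the glycosyltransferase Mgat3 (7.08-fold), Pla2g7 (6.99-fold over 2 probes), the procollagen processing enhancer Pcolce (6.87-fold) and Psmb8. The largest falls were in the apical membrane protein Mal (12.9-fold), Pkp2, the trafficking adaptor Tom1l1 (6.69-fold), Mal2, the vesicle priming factor Unc13b (6.30-fold), Cldn7, maspin, Serpinb5, (5.62-fold) and Dynap (5.37-fold). Ctrb1 (-2.93) and Ino80c (-2.83) belonged to this group by ratio, but their sample channel was higher on the SNAIL-labelled array, at 2.15 and 0.91, and their reference channel was higher still, at 4.76 and 3.54. Among genes above background on 1 array only, Serpinb2 was at least 5.63-fold lower and the cytokine Il1a at least 3.12-fold lower on the SNAIL-labelled array, followed by Samd12 (at least 2.83-fold), Ankrd22 (at least 2.56-fold, with a reference channel brighter by 0.73 on the vector array) and Gca (at least 2.45-fold). Plscr4 was at least 2.53-fold higher, the selectin Sele at least 2.32-fold higher and Ppm1e at least 1.97-fold higher. Bounds for Kcne2 (at least 11.6-fold higher) and Lrrc4c (at least 2.14-fold higher) came with reference channels brighter by 6.73 and 1.07.

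The balance of rises and falls depended on the scaling. Of the changed genes, 62.1% were higher after loess and 23.3% after median centring, which put the median of all genes at -0.21. Relative to that shift, the median was -0.83 for junction genes, 0.06 for mesenchymal genes, -0.03 for matrix genes, 0.07 for transition factors, 0.12 for proteases, -0.02 for TGF-beta response genes and 0.77 for antigen presentation genes. Under median centring, the turn of sign of the mesenchymal, transition factor and protease medians thus came with the shift of all genes. The transition factor median also turned below 0 with the Feature Extraction ratio and the authors' value table. There the median of all genes was 0.03, so that turn did not come with such a shift.

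**Figure D1:**
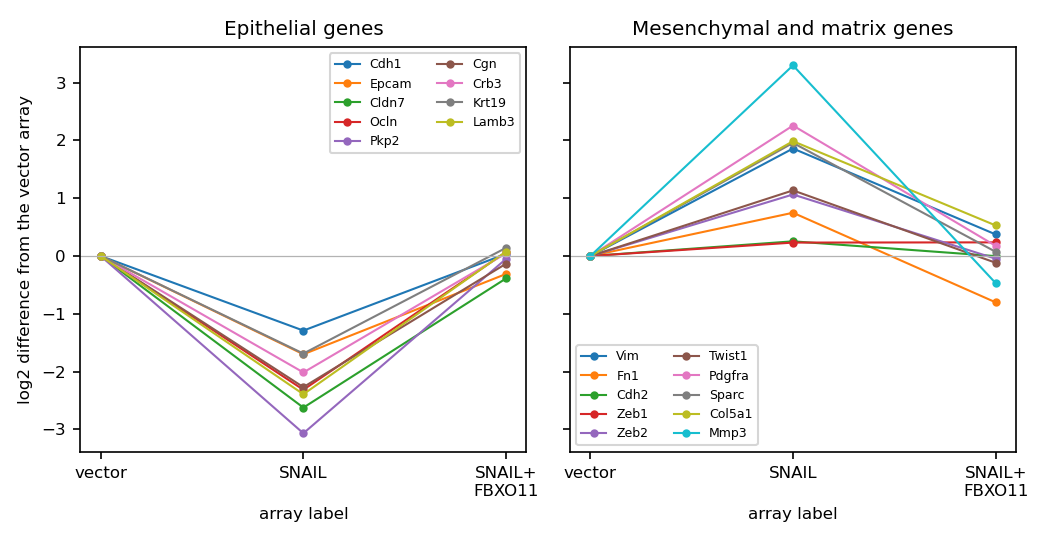
Log2 difference from the vector array (vertical axis) of epithelial genes (left) and of mesenchymal and matrix genes (right) on the 3 arrays, 1 array per label; lines join the values of a gene and there is no error bar because there are no replicates. The epithelial genes shown fell on the SNAIL-labelled array, Pkp2 to -3.07 and Cdh1 to -1.29, and lay nearer to 0 on the SNAIL+FBXO11-labelled array. The genes are a selection. Members of the lists that went the other way on the SNAIL-labelled array, among them Krt23 (2.27), Msn (-1.17), Postn (-1.29) and Sox9 (-1.05), are not shown.

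The second comparison, SNAIL+FBXO11 against SNAIL, asks what differed between the line labelled for both genes and the line labelled for SNAIL alone. These are separate stable lines on 1 array each, and the Fbxo11 probe was not higher in the line labelled for both (-0.49). Many epithelial junction genes were higher on the SNAIL+FBXO11-labelled array. Of 37 measured, 16 rose and 0 fell, with a median of 0.77 (percentile 100). Pkp2 was 8.09-fold higher, Ocln 5.21-fold, Cldn7 4.71-fold and Cgn 4.39-fold. Cdh1 was at 1.33 ± 0.17 by ratio and at 2.31 ± 0.06 in the sample channel alone (SD over 10 spots), but at 0.83 with the Feature Extraction ratio, and Epcam was 2.62-fold higher. Of 39 measured keratin and surface genes, 13 rose and 0 fell, with a median of 0.68 (percentile 100), among them Lamb3 (5.53-fold), the membrane protease St14 (3.67-fold) and the keratin Krt19 (3.55-fold). Of 18 SNAIL-repressed targets, 7 rose and 0 fell (median 0.57, percentile 100), with Crb3 at 2.06. Among 20 epithelial regulators the splicing regulator Esrp2 (1.07, and 0.99 with the normexp fit chosen after seeing the data) was past 2-fold and the median was 0.10 (0.43 with median centring).

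Several mesenchymal genes fell in the same comparison. Vim was 2.80-fold lower, Pdgfra 4.23-fold, the membrane protein Emp3 2.37-fold and S100a4 2.31-fold, which made 4 falls and 0 rises among 34 measured mesenchymal genes (median -0.26, and 0.05 with median centring). With median centring Emp3 (-0.94) and S100a4 (-0.70) were under 2-fold, and S100a4 also in the sample channel alone (-0.73). Of 42 measured matrix genes 5 were past 2-fold lower and 0 higher, including Sparc (3.69-fold), Fn1 (2.93-fold), Loxl3 (2.76-fold) and Col5a1 (2.75-fold), with a list median of -0.11 that was 0.20 with median centring. With the normexp fit chosen after seeing the data it was 0.00. Zeb2 (-1.40) and Twist1 (-1.25) fell among 23 transcription factors of the transition, whose median of -0.23 was 0.04 with median centring, where Twist1 was at -0.96. The Zeb2 value does not rest on the same set of probes as in the first comparison, so the 2 sizes are not alike. Zeb1 differed by 0.00 (0.61 with the Feature Extraction ratio) and Cdh2 by -0.26 (0.10 with median centring). Among 25 protease and protease inhibitor genes 4 fell, including Mmp3 (13.6-fold), Adamts4 (4.85-fold) and the plasminogen activator Plat (2.33-fold), and the median of -0.19 was above 0 with median centring, where Plat was at -0.97. In the TGF-beta list 4 of 28 fell, with Tgfb2 at -1.51, Smad6 at -1.42 and Tgfbr3 at -1.32, and its median of -0.18 was likewise above 0 with median centring. Of 19 measured antigen presentation genes, 7 fell and 0 rose, with a median of -0.84 (percentile 0; -0.46 with median centring). Psmb8 was 6.28-fold lower, B2m 2.57-fold and Psmb9 2.45-fold (-0.94 and -0.99 for the last 2 with median centring), and Nlrc5 was at -1.52 over probes that disagreed, at -2.99 and -0.04.

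Over all genes, 176 rose and 310 fell. The largest rises were in Mal (14-fold), Pkp2, Tom1l1 (6.51-fold), Lamb3, Dynap (5.29-fold), Ocln and Unc13b (4.98-fold). Ctrb1, Ino80c and Gsx1 had ratios of 3.0, 2.84 and 2.32 while their sample channels were lower, at -2.14, -0.87 and -3.39. The largest falls were in Mgp (26.9-fold), Mmp3, Slpi (11.7-fold), Rab7b (9.27-fold), Aqp1 (6.94-fold), the anthrax toxin receptor Antxr1 (6.67-fold), the thrombospondin Thbs3 (6.63-fold over 2 probes), Psmb8, Lrrc75b (6.23-fold) and the inflammatory caspase Casp1 (5.99-fold). By bounds, Serpinb2 was at least 3.65-fold higher and Nfe2l3 at least 2.25-fold higher, and Krt23 was at least 5.33-fold lower, the uncoupling protein Ucp1 at least 4.93-fold, Kctd12b at least 3.39-fold and Angpt1 at least 2.85-fold. Bounds for Tmprss2 (at least 2.85-fold higher), Olfr734 (at least 2.75-fold higher), Olfr1360 (at least 2.63-fold higher) and Kcne2 (at least 10.9-fold lower) came with reference channels brighter by 1.39, 1.32, 1.27 and 6.72. Of the changed genes 36.2% were higher after loess and 70.5% after median centring, which put the median of all genes at 0.18. Relative to that shift the median was -0.13 for mesenchymal genes, 0.01 for matrix genes, -0.14 for transition factors, -0.14 for proteases and -0.05 for TGF-beta response genes, so all of these but the matrix median kept the sign they had after loess.

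The third comparison, SNAIL+FBXO11 against vector, covers the lines that the labels call epithelial. The profiles lay close together, with 1 gene higher and 27 lower by at least 2-fold, against 8 genes in the reference channel. Kifc1, a mitotic kinesin, was the gene that rose (2.32-fold). The largest falls were in periostin, Postn, (3.82-fold), the caveolar protein Cavin2 (3.31-fold), the actin bundling protein Lcp1 (3.20-fold, with probes at -1.68 and -1.67), the actin-binding protein kinase C substrate Marcks (3.18-fold) and Moxd1 (2.80-fold). Besides Postn, the members of the fixed lists that fell were the epithelial sorting adaptor Ap1m2 (2.47-fold), Mal2 (2.26-fold, but -0.80 with offset 0 and -0.27 with the Feature Extraction ratio), the Notch ligand Jag2 (2.40-fold), the drug efflux transporter Abcg2 (2.36-fold) and the chemokines Cxcl5 (2.41-fold) and Cxcl10 (2.02-fold). Junction genes had a median of -0.05, with 0 of 38 past 2-fold either way, and antigen presentation genes a median of -0.01, with 0 of 19, a value that crossed 0 in 4 of the other settings. Epithelial regulators (-0.15, percentile 0.09) and TGF-beta response genes (-0.13, percentile 0.02) had medians that kept their sign in every setting, with no member past 2-fold after loess. Sign was also kept by interferon response (-0.24, percentile 0), cytokine and NF-kB (-0.20, percentile 0) and, the other way, endoplasmic reticulum stress genes (0.13, percentile 100). The medians were -0.03 for keratin and surface genes, -0.04 for SNAIL-repressed targets, 0.03 for mesenchymal genes, 0.03 for matrix genes, -0.05 for transition factors and -0.07 for proteases, and the first 3 of these changed sign in other settings. Cdh1 was at 0.04, Epcam at -0.31, Vim at 0.37, Zeb1 at 0.24, Zeb2 at -0.05 and Cdh2 at 0.00, and Fn1 was at -0.80. Other lists' members with the largest differences under 2-fold were Cldn4 (-0.89), Esrp1 (-0.47), Klf8 (-0.86), Cald1 (-0.52), Adamts4 (-0.87) and Fst (-0.96). Of these, Klf8 and Adamts4 were past 2-fold with offset 0 (-1.05 and -1.01) and with the Feature Extraction ratio (-1.25 and -1.07), and Fst with median centring (-1.04). By bounds, the DNA sensor Aim2 was at least 2.27-fold lower, Aspn lower by a bound just short of 2-fold and Il13 at least 1.80-fold higher, the last with a reference channel brighter by 0.71. Only 3.57% of the changed genes were higher in the main setting, a share that was 38.5% with the authors' ratios and 21.4% in the sample channel alone. The counts were 42 higher and 67 lower with the authors' ratios, and 10 and 45 with offset 0.

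**Figure D2:**
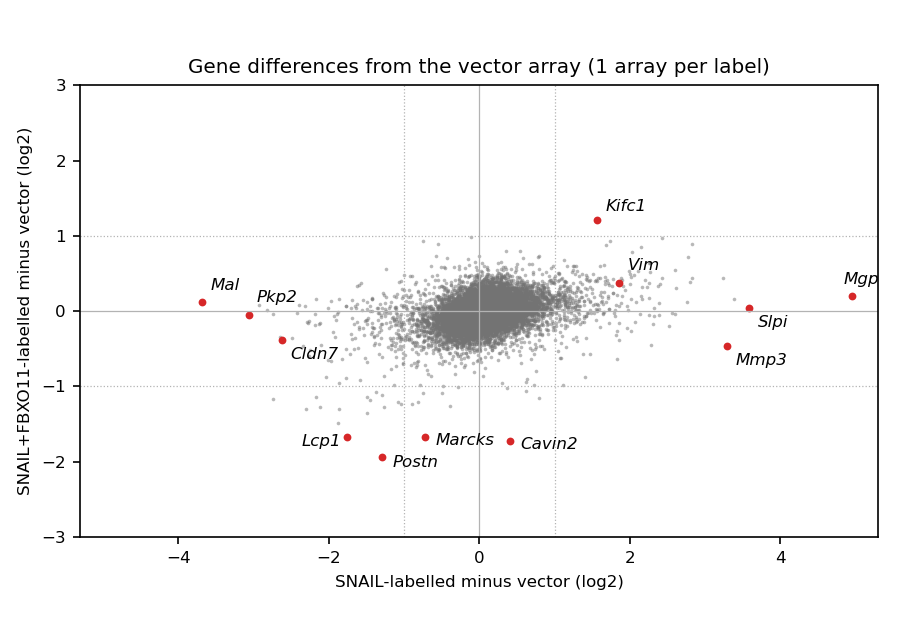
Log2 difference from the vector array of each gene measured in both comparisons, for the SNAIL-labelled array (horizontal axis) and the SNAIL+FBXO11-labelled array (vertical axis), with 1 array per label and dotted lines at 2-fold. The cloud is wider along the horizontal axis (SD over genes 0.39) than along the vertical axis (0.18), and both differences share the vector array.

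The design also asks how far the genes changed on the SNAIL-labelled array lay from vector on the SNAIL+FBXO11-labelled array. Of 349 genes that rose against vector and were measured again, 250 (71.6%) were at least 2-fold lower on the SNAIL+FBXO11-labelled array than on the SNAIL-labelled array, and 348 were within 2-fold of vector. Of 220 that fell, 144 (65.5%) were at least 2-fold higher, and 204 were within 2-fold of vector. In 14 of the 144 and 1 of the 250 the reference channel was itself at least 2-fold apart between arrays. With the reference channel held within 2-fold, the shares were 71.55% and 63.41%. The median of the genes that rose was 1.30 against vector on the SNAIL-labelled array and 0.14 on the SNAIL+FBXO11-labelled array, and that of the genes that fell was -1.33 and -0.17. Independent lists of these sizes would share 6.18 and 2.21 genes. The SNAIL-labelled array enters both differences, so noise on it alone makes them oppose each other, and part of the excess may come from that. The correlation across genes, which are not independent replicates, was -0.89 with a covariance of -0.132, where arrays simulated with spot noise alone gave -0.43 and -0.00574. The reference channel, with the same RNA on every array, gave -0.73 and -0.0168. In that channel 12 of 13 genes that rose and 2 of 7 that fell were at least 2-fold back. The 13 take in 9 genes for which a patch of light on the SNAIL-labelled array is weighed below, so this share does not stand for all genes. With the 2 differences taken from different probes of a gene, the correlation was -0.54 and the covariance -0.0786. For genes with 2 or more probes, choosing genes on 1 probe and measuring them on another gave, for 78 genes that rose, a median of 0.95 on the SNAIL-labelled array and 0.11 on the SNAIL+FBXO11-labelled array, and for 38 that fell, -0.90 and -0.02. The second probe was past 2-fold the same way on the SNAIL-labelled array in 37 of the 78 and 19 of the 38, and at least 2-fold back in 37.2% and 39.5% of all of them, where the first probe was in 70.5% and 65.8%.

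The vector array enters the differences from vector of both other arrays, so noise on it alone makes these differences go the same way. Their correlation across genes was 0.33, with a covariance of 0.0240. In the reference channel, with the same RNA on every array, the values were 0.36 and 0.00604. With that limit, a small set of genes was past 2-fold from vector on both arrays with SNAIL in their label. In it, 16 genes were lower on both, among them Lcp1 (-1.76 and -1.68), Postn (-1.29 and -1.93), Cxcl5 (-1.26 and -1.27) and Abcg2 (-1.04 and -1.24, the former -0.93 with the Feature Extraction ratio), and Kifc1 alone was higher on both (1.57 and 1.22). Of the 16, 3 were nonetheless at least 2-fold nearer to vector on the SNAIL+FBXO11-labelled array, namely Mal2 (-2.74 and -1.17, the latter -0.27 with the Feature Extraction ratio) and, named after their values were seen, Lce1g (-2.31 and -1.30) and Prl3d2 (-2.18 and -1.15). For Prl3d2 the ratio differed by 1.03 from the SNAIL-labelled array while the reference channel differed by -0.52, so part of that move may come from the reference. In 4 genes the SNAIL+FBXO11-labelled array was at least 2-fold below both others, and Akap12 and Samsn1 are named among them after their values were seen: Cavin2 (-2.14 against SNAIL), Samsn1 (-1.95), Akap12 (-1.69) and Cxcl10 (-1.38).

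**Figure D3:**
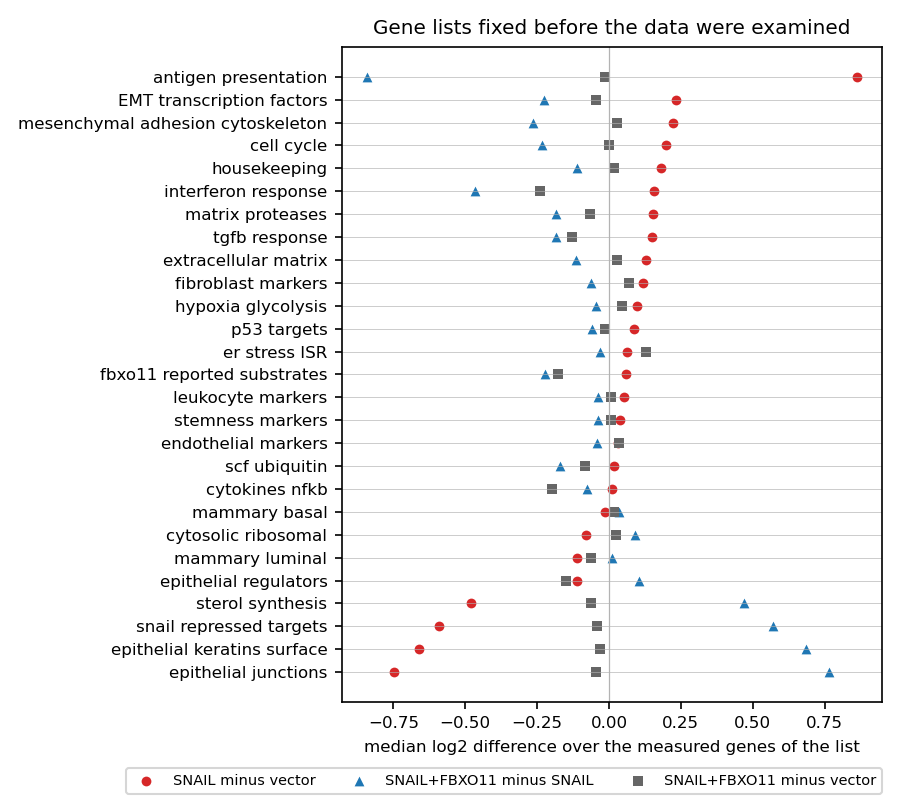
Median log2 difference over the measured genes of each gene list fixed before the data were examined (horizontal axis), for the 3 comparisons between arrays, 1 array per label and no error bar. Junction genes lie at -0.75 for SNAIL minus vector and 0.77 for SNAIL+FBXO11 minus SNAIL, antigen presentation genes at 0.86 and -0.84, and the sign of several smaller medians turned with median centring, as for the matrix genes.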

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

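The tests of the reference channel, of bright patches, of spot spread and of unnamed probes, and 3 of the settings, were chosen after the results were seen. Among probes that the accession match left without a gene name, which no comparison above used, 159 of 21429 measured differed at least 2-fold between the SNAIL-labelled and vector arrays, 114 higher and 45 lower. The reference channel of these probes gave 15. Of the 159, 53 were probes the array names only by a genomic interval, a kind that made up 12158 of the 21429 measured.

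The SNAIL-labelled array stood apart from both others, with 581 genes past 2-fold against vector, where the SNAIL+FBXO11-labelled array had 28. An artefact of the array or its hybridisation that touches both channels is argued against by the reference channel, in which 20 genes differed at least 2-fold, and background correction or normalization by the ratio of the 2 counts, which was 8.43 or more over the settings tried. A mislabelled or exchanged sample cannot be told apart from the design as labelled, because the Snai1 probe differed by -0.37 and its position relative to the insert is not known. The junction median of -0.75, Cdh1 at -2.48 in the sample channel and Vim at 1.86 go with the phenotype labels, but do not address an exchange between the 2 arrays labelled epithelial or with an outside sample. A difference that SNAIL, and FBXO11 with it, makes in these cells remains a hypothesis and was not tested, since each label is 1 culture and any change particular to that culture would look the same.

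In 9 genes that fell by ratio on the SNAIL-labelled array, the reference channel was at least 2-fold brighter there than on the vector array: Ctrb1, Ino80c, Gsx1, Hmbox1, Slc5a5, Utp23, Rnd1, Lif and 1700042O10Rik, named here after their values were seen. Whether their transcripts fell stays open: 0 of the 9 were at least 2-fold lower in the sample channel, but of 29 spots on that array with a reference channel 4-fold brighter than on both others, 24 were at least 2-fold brighter in the sample channel too, which would hide a fall. Extra light on a patch of the array is a candidate explanation, because 8 of the 9 had a probe within 5 rows and columns of another spot with a 4-fold brighter reference channel, where 1.0% of 1000 random spots did. No biological explanation from the design was tested beyond this. The vector array had a similar patch, with 15 spots of a 4-fold brighter reference channel than on both others, 14 of them beside another, which takes in Loxl3.

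The authors' Feature Extraction log ratios spread more over the spots of 1 probe on the SNAIL-labelled array, with a median SD of 0.22 for probes of mean log2 intensity over 10, against 0.04 on each of the other arrays. True noise of the spots is argued against by the loess ratios of the same spots, whose median SD was 0.065. Removal of a spatial trend from 1 channel only may be the source. The file statistics give a fitted trend of 0.161 for the reference channel and 0 for the sample channel of that array, and values above 0 for both channels of the others, with the spread of 0.219 found on that array alone.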

How the results depend on the processing

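The junction list's median kept its sign in each setting (-1.04 to -0.42 for SNAIL minus vector), and no setting brought the SNAIL against vector count near that of SNAIL+FBXO11 against vector. Median centring gave 178 higher and 585 lower genes for SNAIL against vector, 397 and 166 for SNAIL+FBXO11 against SNAIL, a share moved back of 55.7% for SNAIL-lower genes, and matrix medians that reversed to -0.24 and 0.20. The Feature Extraction ratio and the authors' value table each gave 388 lower for SNAIL against vector, 329 higher for SNAIL+FBXO11 against SNAIL, 42 higher and 67 lower for SNAIL+FBXO11 against vector, and a matrix median of 0.05 (0.055 in each). Against vector, SNAIL+FBXO11 had 10 higher and 45 lower with offset 0, 9 higher in the sample channel alone, 2 higher without the filter on dim probes and 4 higher by the brightest probe. In the sample channel alone the matrix medians were -0.0004 and -0.028, and 4 genes reversed: Ctrb1 (2.15 and -2.14), Ino80c (0.91 and -0.87), Loxl3 (-1.84) and Gsx1 (-3.39). The 1.5-fold rule gave 1140 higher and 541 lower, 455 and 1079, and 47 and 106 in the 3 comparisons in the order of the report. The 3-fold rule gave 106 and 66, 49 and 83, and 0 and 4, with 63.1% of SNAIL-higher genes back. The causes were not tested, apart from the size rules, which set their own counts, and the patches of light weighed above. Of settings chosen after seeing the data, the normexp fit without spots of non-uniform background (a background mean of -23.5 in place of -109.3 in the sample channel of the SNAIL-labelled array) gave matrix medians of 0.052 and 0, and the other 2 moved no count by 1.5 times. Of 206 values of named genes, 21 moved by at least 1.5-fold with the Feature Extraction ratio, 15 in the sample channel alone, 14 with median centring, 5 with offset 0 and 5 by the brightest probe. With median centring 24 were no longer past 2-fold, and none that had been past 2-fold changed sign there. They included, for SNAIL minus vector, Zeb2, Twist1, S100a4, Mmp10, Mmp13, Smad6, Tgfbr3, Tgfb2, Pcna, H2-M3, Csf1, Cth and B2m, and for SNAIL+FBXO11 minus SNAIL, Twist1, Emp3, S100a4, Plat, Pcna, B2m, Psmb9, Vcam1, Egln3 and Pfkfb3. With the Feature Extraction ratio the same held for Cdh1 (-0.70), Cth (0.84) and Abcg2 (-0.93) for SNAIL minus vector, Cdh1 (0.83), S100a4 (-0.95), E2f2 (0.93) and Idi1 (0.94) for SNAIL+FBXO11 minus SNAIL, and Mal2 (-0.27) for SNAIL+FBXO11 minus vector, and in the sample channel alone for Zeb2 (just under 2-fold), S100a4 (0.92), Msn (-0.77), Mmp13 (0.73) and Pcna (0.92) in the first and S100a4 (-0.73), Pcna (-0.88) and Asns (0.87) in the second. By the brightest probe Tgfb2 (0.97) and Csf1 (0.94) were under 2-fold for SNAIL minus vector. Aquantile leaves ratios as they are and tests nothing. No replicate exists to leave out, and no paired analysis was possible because each group has 1 array. Signal over background limited dim genes: the sample channel was above background for 18967, 18220 and 17680 genes on the vector, SNAIL-labelled and SNAIL+FBXO11-labelled arrays.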

Other observations

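Further lists describe metabolism and growth. Of 27 measured sterol synthesis genes, 26 were below 0 on the SNAIL-labelled array against vector, with a median of -0.48 (percentile 0), and 26 were above 0 on the SNAIL+FBXO11-labelled array against SNAIL, with a median of 0.47 (-0.93 and 0.74 with median centring). The isoprenoid synthesis enzyme Idi1 was 2.20-fold lower in the first comparison and 2.01-fold higher in the second (0.94 with the Feature Extraction ratio), and against vector the SNAIL+FBXO11-labelled array had a median of -0.06 (above 0 with the authors' ratios), with Fasn at -0.45. Cell cycle genes had medians of 0.20, -0.23 and 0.00 in the 3 comparisons in the order of the report, and the first turned to -0.24 and the second to 0.14 with median centring. The replication clamp Pcna rose 2.24-fold and then fell 2.16-fold, but was under 2-fold with median centring (0.63 and -0.66) and in the sample channel alone (0.92 and -0.88). E2f2 was 2.02-fold higher in the second comparison (0.93 with the Feature Extraction ratio), and Cenpf was at -0.31 in the third. Hypoxia and glycolysis genes had medians of 0.10, -0.05 and 0.04, with Egln3 at 1.66, -1.05 and 0.61, Ddit4 at -1.24 and 1.79 in the first 2, and Pfkfb3 at -1.03 in the second, where Egln3 and Pfkfb3 were at -0.74 and -0.73 with median centring and Pfkfb3 at -0.54 without the filter on dim probes. With median centring each of these medians changed sign, to -0.41, 0.39 and -0.01. Endoplasmic reticulum stress genes had medians of 0.06, -0.03 and 0.13 (the last at percentile 100), of which the first 2 changed sign with median centring, with the Feature Extraction ratio and the authors' value table, and in the sample channel alone. Cth was at 1.06 in the first comparison (0.71 with median centring and 0.84 with the Feature Extraction ratio), and Chac1 (1.23), Trib3 (1.04) and Asns (1.01, and 0.87 in the sample channel alone) were past 2-fold higher in the second, with Chac1 at 0.60 in the third. The p53 targets had medians of 0.09, -0.06 and -0.01, of which the first 2 changed sign in the same settings. Casp1 (2.56) and Fas (1.39) rose and Perp (-1.60) and Plk2 (-1.52) fell in the first, Fas (-1.54) and Perp (1.38) moved the other way in the second, and Plk2 was at -0.63 in the third. Cytosolic ribosomal proteins had medians of -0.08, 0.09 and 0.02, or -0.68, 0.60 and -0.07 with median centring, with no member past 2-fold and Rps26 at -0.61 in the first (-1.22 with that centring) and Rpl35 at 0.24 in the third. Housekeeping genes had medians of 0.18, -0.11 and 0.02, each of the opposite sign with median centring. Relative to the shift of all genes under median centring, the medians in the first and second comparisons were -0.03 and -0.04 for cell cycle, -0.21 and 0.20 for hypoxia, -0.24 and 0.17 for endoplasmic reticulum stress, -0.10 and 0.15 for p53, -0.48 and 0.41 for ribosomal and -0.18 and 0.13 for housekeeping genes. B2m was the housekeeping member past 2-fold, though not with median centring, and Tfrc was at -0.33 in the third.

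Interferon response genes had a median of 0.16 for SNAIL minus vector (-0.15 with median centring, and 0.06 relative to the median of all genes there) and of -0.47 and -0.24 in the comparisons of the SNAIL+FBXO11-labelled array with SNAIL and with vector, both at percentile 0 (-0.15 and -0.27 with median centring). Ifi27 (3.72-fold) and Lgals3bp (2.62-fold) rose and Ifih1 and Bst2 (each 2.09-fold) fell in the first (Ifih1 at -0.60 without the filter on dim probes), while Ifi27 (3.23-fold), Ifit1 (2.90-fold), Lgals3bp (2.74-fold) and Cxcl10 (2.61-fold) were among 7 of 36 that fell in the second. In the antigen presentation list Ciita was at 0.57 in the third, and at 1.05 in the sample channel alone, past 2-fold. Cytokine and NF-kB genes had medians of 0.01, -0.08 and -0.20, of which the first 2 changed sign with median centring. The third was at percentile 0 and kept its sign in every setting. Tslp (1.83), Cx3cl1 (1.51) and Csf1 (1.30 over 3 probes) rose and Cxcl3 (-1.82) was among 6 that fell in the first, and Csf1 (-1.69), Tslp (-1.61), Vcam1 (-1.20) and Cxcl3 (1.18) were past 2-fold in the second. With median centring Csf1 was at 0.94 in the first and Vcam1 at -0.89 in the second. Reported FBXO11 substrates had medians of 0.06, -0.22 and -0.18 over 7 measured genes with none past 2-fold, and SCF ubiquitin genes had medians of 0.02, -0.17 and -0.08, where the first 2 of each list changed sign with median centring. Relative to the shift of all genes there, the first 2 were -0.13 and 0.00 for cytokine and NF-kB genes, -0.13 and -0.05 for FBXO11 substrates and -0.26 and 0.04 for SCF genes. Bcl6 was at 0.58 in the first and 0.36 in the third, and Snai1 at 0.59 in the second. Among SCF genes Fbxl14 was at -0.55 in the first (-1.03 with that centring), Fbxo11 at -0.49 in the second and Cand1 at -0.28 in the third. Luminal mammary genes had medians of -0.11, 0.01 and -0.06, with Krt19 at -1.69 in the first. Basal mammary genes had medians of -0.01, 0.04 and 0.02, with Jag1 (-1.58), Krt14 (-1.53) and Id4 (1.25) past 2-fold in the first and Krt14 (1.21) in the second. Stemness genes had medians of 0.04, -0.04 and 0.01, with Wnt10a at -1.65 and 1.29 in the first 2. Markers of leukocytes (0.05, -0.04 and 0.01), endothelium (0.03, -0.04 and 0.04) and fibroblasts (0.12, -0.06 and 0.07) had small medians. Their members with the largest differences included Cd52 (0.42) and Tyrobp (0.37 in the second and 0.42 in the comparison with vector), the VEGF receptor Flt1 (1.51 and -1.43 in the first 2) and Vwf (0.09 in the third). Among fibroblast markers Pdgfra (2.26), Postn (-1.29) and gelsolin, Gsn, (-1.14) were past 2-fold in the first. Pdgfra (-2.08) and Gsn (1.33) were so in the second, and Postn (-1.93) in the third. Several of these medians near 0 changed sign between settings, and no direction is read from them.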
